A study of Mus musculus with 18 samples.

How the data were processed

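The series holds 4C-seq libraries of mouse splenic B cells with a bait in the intronic enhancer of Igh, prepared with DpnII and Csp6I as first and second enzymes. The submitters' processing notes name Bowtie for the first deposit, Bowtie2 for the LPS libraries and the mm10 assembly; mapping parameters and filters are not stated. The 12 deposited files of resting and LPS + IL4 cells hold raw read counts per interval of 24 bp at a fragment end, per the file headers and as whole numbers; ends without a read are not listed. The 6 deposited files of LPS cultures hold coordinates without a value column: each lists the covered ends, a presence list, so no count or depth can be taken from them. No normalization by the authors was found in either kind of file. Within a file each interval was listed once. Over all 18 libraries 440025 different ends were listed, 56916 of them on chromosome 12. Since the reads carry no molecular identifiers, the counts are of PCR products and not of independent molecules.

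Libraries were grouped by genotype and culture condition as the labels give them, 3 per group. The titles of the 6 WT libraries of the first deposit read WTKO while their genotype label is WT; the label was followed, and every genotype comparison of that deposit rests on it. The labels state neither that replicates are separate animals nor that equal replicate numbers share an animal. Gene positions in mm10 came from the RefSeq table supplied with the data. The items named in the report follow a rule written before the data were examined: 21 elements of the Igh locus (each constant gene with up to 10 kb upstream, the 3' regulatory region of 35 kb and its 4 kb pieces hs3a, hs1,2, hs3b and hs4, the 3' CTCF sites, the 3' flank, the J/D region and the proximal, middle and distal VH segments) and up to 10 windows of 10 kb per comparison with the largest change among those called and with no overlap between groups. Of the windows so named the report gives the ones in different parts of the locus. The 3' regulatory region, its pieces and the 3' CTCF sites were placed at set distances beyond Igha and not by annotation, so their positions are approximate. Ends within 5 kb of the bait were left out, which leaves Ighm with 9 ends. Fixed loci on other chromosomes were compared with random positions.

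Reads were summed per element and per window from 1 Mb on the constant region side to 3 Mb on the VH side. Windows with a mean of at least 10 reads were kept (399). Counts were fitted with edgeR 4.0.16 (quasi-likelihood with robust spread, group means, library size the reads on chromosome 12 outside the bait neighbourhood, no TMM factors) in R 4.3.3, over the 12 libraries together. P-values were two-sided and adjusted by Benjamini-Hochberg over the elements and over the windows apart, with a threshold of 0.05. For the LPS libraries edgeR could not be used on counts and was run on covered ends as an alternative only. The reported form was limma 3.58.1 on the log2 share of covered ends with a pseudocount of 1, the fallback planned before the data were examined. A limma model on the log odds of covered ends with depth as a covariate was run before it; the planned form then became the reported one, and the log odds forms stand among the alternatives. Genotype over conditions and library measures were tested by exact permutation within conditions. The planned test over 3 conditions was limited to the 2 conditions with reads, and over all 3 was run on covered ends.

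Alternatives were TMM factors, the reads within 1 Mb as library size, DESeq2 1.42.0, no filter on low windows, windows of 5 and 20 kb, bait neighbourhoods of 2 and 10 kb, covered ends in place of reads, reads capped at the 99th percentile, only the compared groups, all 18 libraries together, a replicate block, and each library left out in turn. Leaving out an unlabelled set of 86 fragment ends, taking the library sets they define as a block, and leaving out mutant replicate 1 on both days were added after the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 did the rest.

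The fits were tested on simulated data built from the real libraries. In 10 runs of the WT activation comparison, 90% of elements with a log2 change of 1 were called, 25% with 0.5 and 0% with 0.25, with 1 false call among 150 unchanged elements; over the 4 activation and genotype comparisons recovery was 90% to 100% at 1 and 25% to 50% at 0.5, with 1 to 5 false calls. For windows of the WT activation comparison 3% were called at a log2 change of 1 and 36% at 2, with 3 false calls among 3590; over the 4 comparisons it was 3% to 12% at 1 and 35% to 36% at 2, with 1 to 4 false calls. For the LPS comparison 5.5% of windows with a log2 change of 1 were called, and the median estimate was 0.48, below the simulated change. The simulation was first run with changes of up to 1 and then widened, because few windows were recovered.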

Results

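The contacts of the intronic enhancer of the immunoglobulin heavy chain locus (Igh) were measured by 4C-seq, in which all fragments ligated to a single bait are amplified and sequenced. The bait lay in the enhancer Eμ on mouse chromosome 12 (mm10, 113426025 to 113426048). The cells were splenic CD43-negative B cells, wild type (WT) or mutant for Med1, a subunit of the Mediator complex that links enhancers to RNA polymerase II. Cells were taken resting, after 2 days with LPS and IL4 (which direct switching to Ighg1 and Ighe), or, in a later deposit, after 2 days with LPS alone (which directs switching to Ighg3 and Ighg2b). Each of the 6 groups had 3 libraries, 18 in all. The 12 libraries of the first deposit held between 2470497 and 21074434 reads and covered between 46417 and 112113 fragment ends. The mutant LPS + IL4 replicate 2 was the deepest and the mutant resting replicate 1 the shallowest. Apart from that replicate 2, each mutant library held fewer reads (at most 3378893) than each WT library (at least 3738095). At rest the mutant libraries covered 46417 to 48538 ends and the WT libraries 51568 to 58999. Depth thus differs with genotype, and no genotype comparison of this deposit took it as a covariate beyond library size. The 6 LPS libraries list covered ends without read numbers, between 47312 and 65512 per library, so their depth is unknown. The growth protocol in the labels of WT LPS + IL4 replicate 2 names anti-CD40 with IL4, and the files do not show whether the culture or only the entry differed. The titles of the 6 WT libraries of the first deposit read WTKO, and their genotype label, WT, was followed. 4C-seq does not measure Med1 RNA or protein, so the loss of Med1 could not be checked in these data.

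Shares below are percentages of the reads on chromosome 12 that lay over 5 kb from the bait, given as mean ± SD over 3 libraries. Log2 changes are edgeR estimates ± SE, with p adjusted by Benjamini-Hochberg over 21 elements of the locus fixed in advance. All tests were two-sided. The 12 libraries fell into 2 sets that no label names. At each of 86 ends between 113150941 and 113506498, at least 5 of the 6 libraries of mutant replicates 2 and 3 and WT replicate 3 had at least 50 reads and the other 6 all had fewer. The share of reads at these ends in the latter 6 was 0.151% of that in the former 6. Genotype changes are therefore also given within the first set, which has few reads at these ends (1 mutant and 2 WT libraries per condition), and within the second set, which is well read there (2 mutant and 1 WT).

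The first question was what activation with LPS and IL4 does to the contacts of the enhancer in WT cells. Contacts fell over Ighd, the interval from Ighd to Ighg3 and the distant 3' flank, and rose over Ighg1, Ighe and the 3' regulatory region (3'RR), the enhancer cluster downstream of Igha that is needed for switching. The Ighd unit, the constant gene next to Ighm, fell from 7.44% ± 0.363 to 3.18% ± 0.165 (n = 3 each), a log2 change of -1.23 ± 0.08 (adjusted p = 4.0e-10). Ighg1, the main target of IL4, rose from 0.990% ± 0.123 to 2.50% ± 0.143, a log2 change of 1.33 ± 0.12 (adjusted p = 2.5e-08). Ighe, the IgE constant gene, rose from 0.708% ± 0.0755 to 1.28% ± 0.143 (log2 0.85 ± 0.14, adjusted p = 4.9e-05). The 3'RR (113221204 to 113256203) rose from 12.6% ± 0.996 to 19.0% ± 1.91 (log2 0.59 ± 0.11, adjusted p = 1.1e-04).

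In WT cells 11 of the 21 elements passed an adjusted p of 0.05, 7 higher and 4 lower after activation. Within the 3'RR, the pieces at the approximate positions of the enhancers hs3a, hs1,2 and hs3b rose (log2 0.96, 0.82 and 0.94). The hs4 piece had a log2 change of -0.21 (adjusted p = 0.118). The interval between Ighd and the Ighg3 unit fell by 1.17 on the log2 scale, and the 3' flank fell by 0.58 up to 500 kb from the bait and by 0.53 from there to 1 Mb. The middle VH segments, 500 kb to 1.5 Mb upstream, rose by 0.27. The elements nearest the bait, Ighm (log2 -0.12, adjusted p = 0.449) and the J/D region (-0.04, adjusted p = 0.740), did not pass in the main fit. The J/D region passed as lower in 3 alternatives and Ighm in 1. Within the J/D region, windows of 10 kb starting at 113426025 (log2 -1.18 ± 0.29, adjusted p = 0.0217) and 113436025 (-1.44 ± 0.35, adjusted p = 0.0185) were called as lower. Ighg3, which LPS alone targets, had a log2 change of -0.27 that did not pass (adjusted p = 0.0739). It passed in 5 alternatives and not in 15. Among the 5 were the fits without WT LPS + IL4 replicate 1 (0.0213) and with TMM scaling (0.0385). The rise of the 3'RR was lost with each end capped at the 99th percentile of the covered chromosome 12 ends of its library. The log2 change of the 3'RR was then 0.03 (adjusted p = 0.753), and hs3a (0.13), hs1,2 (0.09) and hs3b (0.11) were not called either. Covered chromosome 12 ends rose from a WT mean of 8450 at rest to 11156 after activation, so more ends were capped there. How far this lowered the change was not tested. With each covered end counted once, the 3'RR (-0.32), its 3 pieces, Ighg1 (-0.14) and Ighe (-0.16) turned sign without passing, and Ighd was not called (-0.37, adjusted p = 0.192). That measure is relative to all covered ends of chromosome 12, which increased: the covered part of the elements themselves went from 68.1% to 81.4% for Ighg1, from 67.1% to 79.4% for Ighe and from 75.1% to 79.3% for the 3'RR. The hs3a call was lost without WT resting replicate 2 (adjusted p = 0.0666) or WT LPS + IL4 replicate 3 (adjusted p = 0.0556). The middle VH call was lost with TMM scaling (adjusted p = 0.0527). Apart from the fits with single libraries left out, its log2 change ranged over the alternatives from 0.02 to 0.32, with an adjusted p of up to 0.857.

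**Figure D1:**
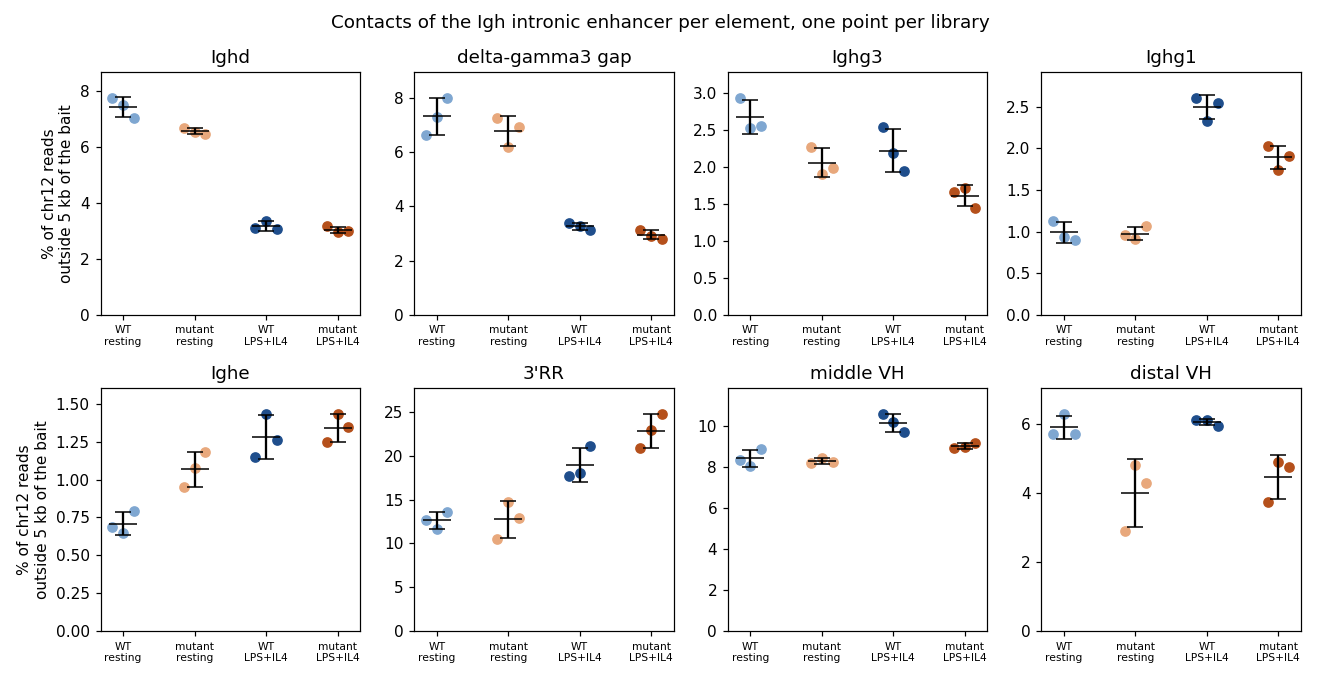
Share of chromosome 12 reads outside 5 kb of the bait (percent, vertical axis) for 8 elements in each of the 4 groups of the first deposit; points are libraries, bars are mean ± SD, n = 3. Ighg1 rose from 0.990% to 2.50% in WT and from 0.977% to 1.89% in the mutant.

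Of 399 windows of 10 kb, 18 changed in WT cells on activation, 7 higher and 11 lower. The window at 113396025 to 113406024, between Ighd and Ighg3, fell by 1.44 ± 0.11 on the log2 scale (adjusted p = 3.8e-08), and the window at 113326025 to 113336024, in the Ighg1 unit, rose by 1.16 ± 0.18 (adjusted p = 3.4e-04). The window at 113136025 to 113146024, in the 3' flank, fell from 4486 ± 858 to 1723 ± 242 CPM (relative to the chromosome 12 reads outside 5 kb of the bait). The window at 112426025 to 112436024 held 0.132 ± 0.229 CPM at rest and 150 ± 149 after activation, where the SD is about as large as the mean. Without WT LPS + IL4 replicate 2, whose label names anti-CD40, 10 windows passed, and without WT resting replicate 1, 11 passed.

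Activation of Med1 mutant cells changed many of the same elements. Ighd fell from 6.57% ± 0.111 to 3.04% ± 0.116 (log2 -1.11 ± 0.08, adjusted p = 1.8e-09). Ighg1 rose from 0.977% ± 0.0802 to 1.89% ± 0.143 (log2 0.95 ± 0.12, adjusted p = 2.2e-06). The 3'RR rose from 12.7% ± 2.11 to 22.9% ± 1.93 (log2 0.84 ± 0.11, adjusted p = 2.2e-06). Ighe went from 1.07% ± 0.116 to 1.34% ± 0.0920, a log2 change of 0.33 ± 0.14 that did not pass (adjusted p = 0.0525). It passed in 10 alternatives and not in 11. Among the 10 were the replicate block and the fits without mutant LPS + IL4 replicate 1 (0.0423) or mutant resting replicate 3 (0.0357).

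In the mutant 11 elements passed, 6 higher and 5 lower, of which 9 were also called in WT, all 9 in the same direction. Besides those above, hs3a (log2 1.13), hs1,2 (0.99), hs3b (0.78) and Ighg2b (0.42, adjusted p = 0.0197) rose, and Ighg3 fell by 0.35 (adjusted p = 0.0197). The activation effects in WT and mutant had a Pearson r of 0.943 and a Spearman rho of 0.920 across the 21 elements, and of 0.245 and 0.321 across the 399 windows; elements and windows are not independent replicates. Of the 399 windows 12 passed, 6 in each direction, among them 113246025 to 113256024 in the 3'RR around hs3a (log2 1.22 ± 0.23, adjusted p = 0.00949). As in WT, the 3'RR rise was not called with capped ends (log2 0.07, adjusted p = 0.567), nor were hs3a (0.12), hs1,2 (0.27), hs3b (-0.12) and Ighg3 (adjusted p = 0.0586). With each covered end counted once the 3'RR turned to -0.43 (adjusted p = 0.0028), Ighg1 to -0.34 (adjusted p = 0.0493) and Ighg2b to -0.46 (adjusted p = 0.035), and hs3a, hs1,2 and hs3b turned sign as well, while the covered part of each element went from 74.5% to 84.1% for the 3'RR, from 66.7% to 81.4% for Ighg1 and from 72.8% to 81.6% for Ighg2b. The Ighg3 call was lost without mutant resting replicate 1 (adjusted p = 0.0925), mutant LPS + IL4 replicate 3 (0.0957) or mutant replicate 1 on both days (0.0969), and the Ighg2b call without mutant resting replicate 1 (adjusted p = 0.0925), mutant LPS + IL4 replicate 2 (0.0567) or mutant replicate 1 on both days (0.119).

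**Figure D2:**
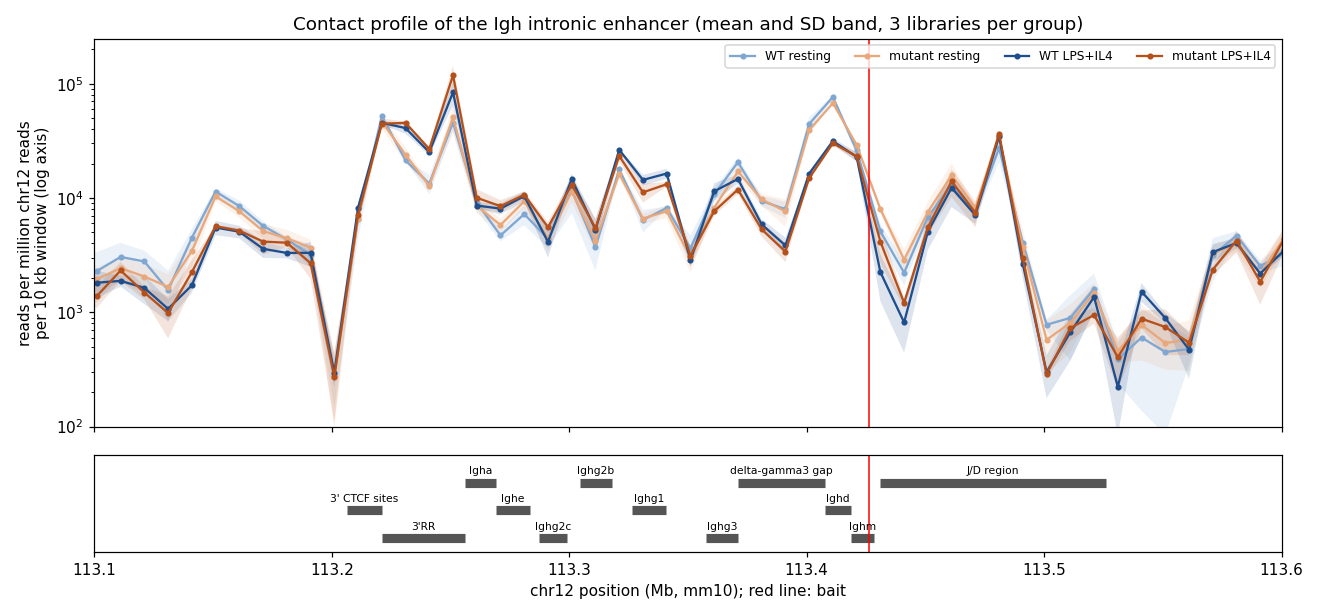
Contact profile along chromosome 12 (Mb, mm10; horizontal axis) in CPM of chromosome 12 reads per 10 kb window, on a log axis, as the mean with an SD band over 3 libraries per group, above a map of the elements. After activation the lines of both genotypes lie lower between Ighd and Ighg3 and higher over Ighg1 and most of the 3'RR.

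The series title asks whether Med1 affects the change of contacts during switching, which is the difference between the activation effects. By the estimates, Ighe gained less in the mutant (log2 difference -0.52 ± 0.20, adjusted p = 0.342), as did Ighg1 (-0.38 ± 0.17, adjusted p = 0.386), but neither difference passed the test. For the 3'RR the difference was 0.26 (adjusted p = 0.675). With edgeR 0 of 21 elements and 0 of 399 windows passed, against 2 elements and 11 windows at an unadjusted p under 0.05. DESeq2 called 0 elements and 4 windows. The interaction was not simulated. In the simulated activation and genotype comparisons only 25% to 50% of elements with a log2 change of 0.5 were called. Differences of the size estimated for Ighe and Ighg1 could therefore be missed.

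**Figure D3:**
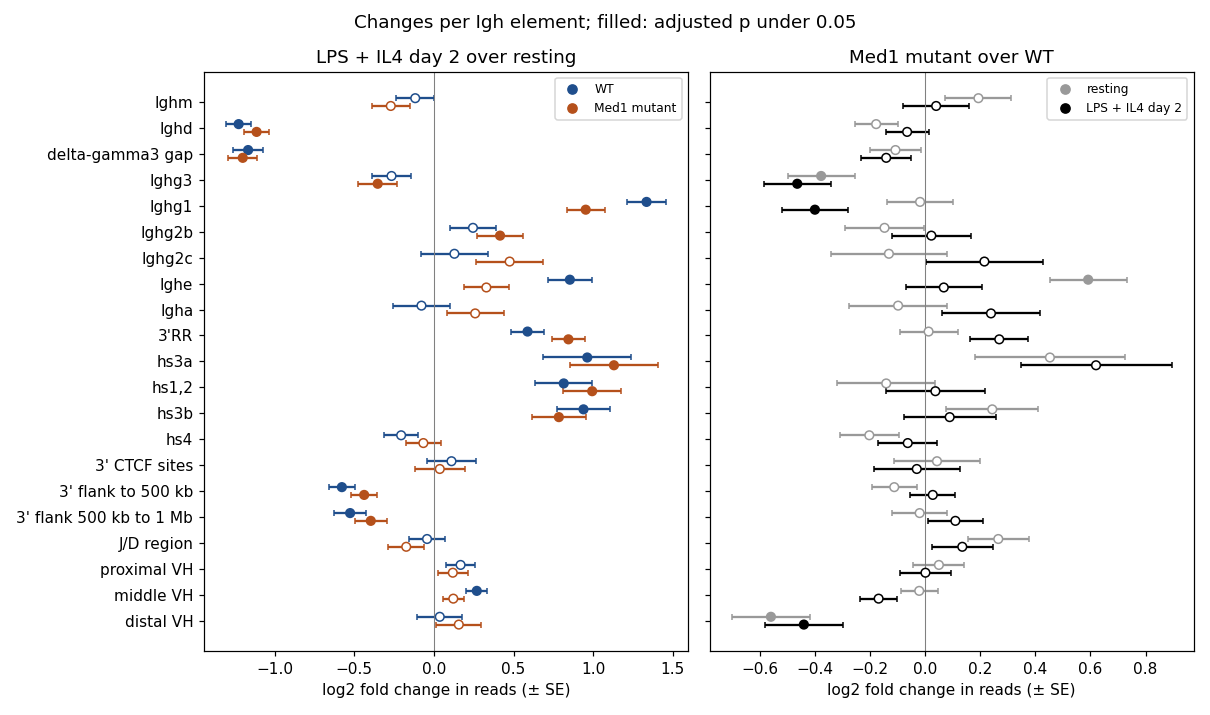
Log2 fold changes ± SE (horizontal axis) of the 21 elements, for LPS + IL4 day 2 over resting in each genotype (left) and for Med1 mutant over WT in each condition (right), n = 3 libraries per group; filled points have an adjusted p under 0.05. The activation changes of Ighd (-1.23 in WT and -1.11 in the mutant) exceed the genotype changes, of which the largest called is 0.59, for Ighe at rest.

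The next question was whether the mutant differs from WT before activation. At rest, Ighe had a higher share in the mutant (1.07% ± 0.116 against 0.708% ± 0.0755 in WT, log2 0.59 ± 0.14, adjusted p = 0.0115). The distal VH segments, 1.5 to 2.6 Mb upstream, had a lower share (4.00% ± 0.989 against 5.90% ± 0.331, log2 -0.56 ± 0.14, adjusted p = 0.0115), and so did Ighg3 (2.05% ± 0.194 against 2.67% ± 0.227, log2 -0.38 ± 0.12, adjusted p = 0.0436). In each case the 3 mutant libraries lay on the same side of all 3 WT libraries. Ighg1 (0.977% and 0.990%) and the 3'RR (12.7% and 12.6%) had similar means in both genotypes.

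Within the first and second library sets the resting log2 changes were 0.51 and 0.51 for Ighe, -1.05 and -0.33 for distal VH and -0.26 and -0.39 for Ighg3. With edgeR, 0 of 399 windows passed, 38 had an unadjusted p under 0.05, and DESeq2 called 14. TMM and DESeq2 scaling shifted the median element by 0.12 and 0.13 (log2) toward the mutant and ended the Ighg3 call (log2 -0.26 and -0.24, adjusted p = 0.222 and 0.382), as did 6 further alternatives. Without WT resting replicate 2 none of the 3 elements passed (adjusted p = 0.0501 for each); Ighg3 was also lost without mutant resting replicate 2 (0.154), mutant resting replicate 3 (0.168) or WT resting replicate 1 (0.231), and Ighe with each covered end counted once (log2 0.12, adjusted p = 0.898).

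After activation with LPS and IL4, 3 elements passed in the main fit with a lower share in the mutant and none with a higher one. The 3'RR passed as higher in the mutant in 7 alternatives and hs3a in 6. Among these was the block that pairs mutant and WT libraries of equal number. Ighg1 had 1.89% ± 0.143 in the mutant against 2.50% ± 0.143 in WT (log2 -0.40 ± 0.12, adjusted p = 0.039). Ighg3 had 1.61% ± 0.143 against 2.22% ± 0.297 (log2 -0.46 ± 0.12, adjusted p = 0.0279), and distal VH 4.46% ± 0.636 against 6.05% ± 0.0987 (log2 -0.44 ± 0.14, adjusted p = 0.0462). The 3'RR had 22.9% ± 1.93 against 19.0% ± 1.91, a log2 change of 0.27 ± 0.11 that did not pass (adjusted p = 0.0882). Ighe, with 1.34% ± 0.0920 and 1.28% ± 0.143, had a log2 change of 0.07.

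Within the first and second library sets these log2 changes were -0.29 and -0.48 for Ighg1, -0.51 and -0.29 for Ighg3, -0.71 and -0.30 for distal VH, and 0.22 and 0.17 for the 3'RR, where 16 of the 86 ends lie and hold 11.7% of its reads in the second set. With edgeR, 0 of 399 windows passed, 6 had an unadjusted p under 0.05, and DESeq2 called 0. The calls depend on the scaling: TMM and DESeq2 shifted the median element by 0.20 and 0.18 (log2) toward the mutant, so that Ighg1 (-0.20 and -0.21), Ighg3 (-0.26 and -0.28) and distal VH (-0.24 and -0.27) were not called, while the 3'RR was (0.46 and 0.44, adjusted p = 0.00891 and 0.00366), as in 5 other alternatives. With capped ends Ighg1 and distal VH were not called (adjusted p = 0.275 each), and with covered ends none of the 3 was. They also depend on single libraries: 0 elements passed without mutant LPS + IL4 replicate 3, WT LPS + IL4 replicate 1 or WT LPS + IL4 replicate 2, 1 passed without mutant LPS + IL4 replicate 2 or WT LPS + IL4 replicate 3, and 2 passed without mutant LPS + IL4 replicate 1. The distal VH call was lost whichever of the 6 libraries was left out (adjusted p from 0.0626 to 0.153).

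Resting and LPS + IL4 libraries together give a genotype test that does not rest on a model of the spread: an exact permutation of the genotype labels within each condition (400 arrangements, smallest p = 0.005). Distal VH had a log2 difference of -0.52 (mutant over WT) and Ighg3 of -0.42, both lower in the mutant in 2 of 2 conditions and both at that smallest exact p (0.005, adjusted p = 0.0525). Ighe had a log2 difference of 0.33 (exact p = 0.03, adjusted p = 0.128). With this test 0 of 21 elements passed correction, and 6 had an exact p under 0.05. Distal VH and Ighg3 already had the smallest exact p, 0.005. Over 21 elements they could pass only if further elements also had very low p-values. That they did not pass therefore does not argue against a difference. The test takes the 12 libraries as separate, and the labels do not say whether equal replicate numbers on both days are the same animal. With the mean of both days per number as the unit, 20 arrangements remain, and distal VH and Ighg3 had an exact p of 0.1, the smallest possible (adjusted p = 0.3), so that form could not call any element. Without WT LPS + IL4 replicate 3, 3 elements passed: Ighg3, distal VH and the J/D region (adjusted p = 0.035 each). That library is the only WT LPS + IL4 library well read at the 86 ends, of which 16 lie in the J/D region (14.6% of its reads), and the J/D log2 changes within the first and second sets were 0.34 and 0.08 at rest and 0.16 and -0.06 after activation. With covered ends in place of reads, over all 3 conditions, distal VH passed (-0.25, exact p = 0.00125, adjusted p = 0.0262). This form also takes the libraries as separate, and shares of covered ends can depend on depth. The mutant covered fewer ends than WT on average at rest (47186 against 55593) and with LPS (50807 against 56808). With LPS + IL4 its mean was higher (74297 against 62493), which rests on the deepest library, mutant replicate 2 (112113 ends). Mutant replicates 1 and 3 covered 49529 and 61248 ends, and the WT libraries 59149 to 68327.

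The whole profile also moved. The share of reads on chromosome 12 rose on activation from 48.1% ± 0.386 to 57.3% ± 1.30 in WT and from 48.2% ± 1.03 to 56.2% ± 1.02 in the mutant, by 8.59 percentage points over both genotypes (exact permutation p = 0.005, adjusted p = 0.04 over 32 tests). The constant region from Ighm to Igha fell from 27.3% ± 0.404 to 21.8% ± 0.293 in WT and from 25.6% ± 0.786 to 20.1% ± 0.725 in the mutant. That was a change of -5.51 points (exact permutation p = 0.005, adjusted p = 0.04). Its denominator, the chromosome 12 reads outside 5 kb of the bait, was a larger part of all reads after activation. As a share of all reads the fall of the constant region, like other falls on activation, would be smaller. The same region was lower in the mutant than in WT by -1.68 points over both conditions (exact permutation p = 0.005, adjusted p = 0.04), with all 3 mutant libraries below all 3 WT libraries in each condition. Within the first and second library sets it was -0.843 and -2.19 points at rest and -1.06 and -1.78 after activation. With the mean of both days per replicate number as the unit all 3 mutant numbers lay below all 3 WT numbers; the exact p is then 0.1, the smallest that 20 arrangements can give, so this test could not make a call either way. The share within 1 Mb of the bait went from 67.7% ± 1.95 to 66.1% ± 1.65 in WT (exact permutation p = 0.4) and from 67.3% ± 1.23 to 68.8% ± 0.948 in the mutant (exact permutation p = 0.2), opposite directions that average to -0.00704 points. After activation it was higher in the mutant by 2.73 points (exact permutation p = 0.1, the smallest possible), and by 3.05 and 1.16 points within the first and second library sets. Single comparisons of 3 against 3 libraries cannot give an exact p below 0.10.

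The LPS cultures, which direct switching to Ighg3 and Ighg2b, could be compared between genotypes only through the ends covered. In WT 84.4% ± 2.46 of the Ighg3 ends and 85.0% ± 7.17 of the Ighg2b ends were covered (n = 3), and in the mutant 79.0% ± 3.23 and 76.2% ± 6.23. Relative to all covered ends of chromosome 12, the log2 difference was 0.17 ± 0.19 for Ighg3, 0.11 ± 0.18 for Ighg2b and -0.04 ± 0.18 for distal VH. In simulated windows with a log2 change of 1 this form returned a median of 0.48, below the simulated change; elements were not simulated in this form. With limma, 0 of 21 elements and 0 of 134 windows passed, against 0 and 7 at an unadjusted p under 0.05. As an alternative, edgeR on covered ends called none either. DESeq2 was not run on these libraries. On other chromosomes the LPS libraries shared more of their covered ends with one another (median phi 0.261 over 15 pairs) than those of the first deposit (0.187 over 66 pairs), most of all mutant LPS replicate 2 with WT LPS replicate 3 (0.446). A limma model on log odds with a depth covariate, outside the plan, called 1 element, Ighm (log2 -2.09, adjusted p = 0.0183), where the planned form gave 0.04. In the first deposit, where both measures exist, the sign in covered ends was that of the reads for 2 of the 3 elements called between genotypes at rest, 3 of 3 after LPS + IL4, and 5 of the 11 called in activation of either genotype. The log2 changes by both measures had a Pearson r of 0.566 and 0.623 for these genotype comparisons and of 0.338 and 0.244 for WT and mutant activation across the 21 elements, which are not independent replicates.

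Side by side, Ighg1 ends were covered at 81.4% ± 7.17 in WT and 81.4% ± 8.04 in the mutant after LPS + IL4, and at 69.1% ± 3.04 and 61.1% ± 3.16 after LPS alone. The 3'RR was covered at 79.3% ± 5.85 and 84.1% ± 8.31 after LPS + IL4 and at 85.5% ± 3.01 and 81.9% ± 7.83 after LPS alone. Of the 86 ends, 16 lie in the 3'RR. The first set, with 2 of 3 WT and 1 of 3 mutant libraries, covered between 36.0% and 37.2% of the 86 ends after LPS + IL4 and the second set between 98.8% and 100%, and the LPS libraries covered between 68.6% and 95.3%. Stimulus, deposit and end set cannot be told apart here, so no test was made.

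Outside chromosome 12, 9 loci fixed in advance were compared with 1000 random positions of their own chromosome, in windows of 250 kb either side. Igl, the lambda light chain locus on chromosome 16, was at percentile 98.7 by reads and 100 by covered ends. Igk, the kappa light chain locus on chromosome 6, was at 84.8 and 97.5, and Pim1, a kinase gene and known target of AID, at 97.4 and 90.7. Myc, a frequent partner of Igh translocations, was at 76.8 and 46.3, and Pvt1, Pax5, Cd83, Bcl6 and Il4ra lay between 69.8 and 96.4 by reads and between 34.5 and 74.9 by covered ends. In the test of genotype over 3 conditions, 0 of the 9 loci passed (exact permutation, lowest adjusted p = 0.261), with 1 at an unadjusted p under 0.05.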

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

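The alternatives were fixed before the data were examined, except those on the end sets, on log odds of covered ends, on mutant replicate 1 and on the replicate number as the unit, which were chosen after seeing the data. Of the values that answer a comparison, 371 were the same under an alternative and 31 moved. The cause was not tested for any of them. A count of calls was taken as the same if it was equal or of similar size, whichever items were called. No calls in both forms was therefore the same. The 371 include single comparisons of library measures, whose exact p cannot fall below 0.1 with 3 against 3 libraries. The 371 is thus no measure of how firm the calls are.

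Counting each covered end once gave 4 elements for WT activation (5 with all 18 libraries in 1 fit), against 11 from reads, and 0 windows (0) against 18. It gave 2 mutant activation windows (2) against 12, 1 resting genotype element (1) and 0 LPS + IL4 genotype elements (1) against 3 each, and 1 element in the genotype test over 3 conditions against 0. In resting WT cells 68.1% of Ighg1 ends were already covered, so this measure has less room to rise than reads. Signs turned for WT activation in Ighg1 (-0.14), Ighe (-0.16), 3'RR (-0.32), hs3a (-0.38), hs1,2 (-0.35) and hs3b (-0.33), and for mutant activation in Ighg1 (-0.34), Ighg2b (-0.46), 3'RR (-0.43), hs3a (-0.60), hs1,2 (-0.31), hs3b (-0.62) and the 3' CTCF sites (-0.46). For Ighg3 at rest the genotype change turned to 0.0492. With all 18 libraries in 1 fit these 14 values differed by less than 0.01. Capping reads at the 99th percentile turned hs3b in mutant activation to -0.12, and gave 7 mutant activation windows and 1 LPS + IL4 genotype element.

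DESeq2 called 26 windows for mutant activation against 12, 14 for the resting genotype against 0 and 4 for the interaction against 0. TMM called 1 element for the LPS + IL4 genotype against 3. For the same comparison the replicate block gave 5 elements, the end sets as a block 6, that block without the 86 ends 6, and leaving out mutant replicate 1 on both days 5. The log odds with a depth covariate called 1 LPS element against 0, Ighm, at -2.09.

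With single libraries left out, elements called ranged from 0 (without WT resting replicate 2) to 4 (without WT resting replicate 3) for the resting genotype, 0 to 2 for the LPS + IL4 genotype and 0 to 3 for the genotype over conditions (3 without WT LPS + IL4 replicate 3), and windows from 10 (without WT LPS + IL4 replicate 2) to 21 for WT activation. Left-out libraries leave 2 in a group, and the spread is pooled over groups.

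With the replicate number as a block, 12, 15, 4, 5 and 0 elements were called for WT activation, mutant activation, the resting genotype, the LPS + IL4 genotype and the interaction, and 0 for LPS; windows were 19, 14, 0, 0, 0 and 0. The labels do not state that equal numbers share an animal. Centred resting and activated libraries with equal numbers correlated at -0.07, 0.07 and -0.06 in WT (1 of 3 best with its own number) and at 0.26, 0.14 and 0.10 in the mutant (3 of 3). The 2 end sets also follow the number on both days, within each genotype, for all 6 numbered pairs, and both replicate 2 pairs had the lowest coverage of chromosome Y ends (0.444% on both days in the mutant, 0.477% and 0.463% in WT). These are hints of shared animals from the data and not from the design; the fit without the block was fixed before the data were examined. Among the elements the block added calls and ended none. In WT activation it added Ighg3 (-0.27), and in mutant activation Ighm (-0.27), Ighg2c (0.50), Ighe (0.33) and the J/D region (-0.18). Between genotypes it added the J/D region at rest (0.28), and the 3'RR (0.27) and hs3a (0.61) after LPS + IL4. The genotype block joins mutant and WT libraries of equal number, which cannot share an animal. Such pairs correlated at -0.10, -0.13 and -0.06 at rest (0 of 3 best with its own number). After LPS + IL4 they correlated at -0.05, 0.04 and -0.09 (1 of 3), so neither the labels nor these correlations bear out that pairing. Other values partly follow the number across genotypes. Replicate 2 had the lowest chromosome Y coverage in both genotypes, and replicates 1 and 3 each fell in the same end set in both. Replicate 2 did not. What equal numbers share across genotypes was not tested. TMM, DESeq2 and capping could not be run on LPS libraries, which hold no reads; all 18 libraries in 1 fit could be run on covered ends only. Few simulated window changes under a log2 of 2 were called; whether depth or the spread between libraries limits them was not tested.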

Other observations

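The tests on fragment ends, on distal VH and on shared ends below were chosen only after the patterns were seen; the splits of the libraries were planned.

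By reads, the 3' CTCF sites, Igha and hs4 did not pass the edgeR test on activation in either genotype. The 3' CTCF sites (hs5 to hs7), where the locus ends, held 1.29% ± 0.250 of reads in resting and 1.39% ± 0.0366 in activated WT cells, and 1.33% ± 0.272 and 1.36% ± 0.0465 in the mutant (n = 3 each). Igha, the IgA constant gene next to the 3'RR, held 0.944% ± 0.158 and 0.894% ± 0.0665 in WT, and 0.881% ± 0.139 and 1.05% ± 0.228 in the mutant. The hs4 piece was the most read of the 4 pieces of the 3'RR in resting cells, with 4.59% ± 0.254 in WT and 3.98% ± 0.422 in the mutant. After activation it held 3.98% ± 0.253 and 3.81% ± 0.525. hs3a held 1.66% ± 0.461 and 2.27% ± 0.619 at rest and 3.23% ± 0.771 and 4.96% ± 1.31 after activation. With ends capped at the 99th percentile hs4 fell on activation, by 0.32 in WT and by 0.42 in the mutant on the log2 scale. Between genotypes 0 of these 4 elements passed in the main edgeR fit and 1, hs3a after activation, had an unadjusted p under 0.05. Among the alternatives hs3a passed in 2 at rest and in 6 after activation. DESeq2 called it in both conditions (0.57 at rest and 0.78 after activation), and edgeR with the replicate block after activation. Of the hs3a reads in the libraries well read at the 86 ends, 24.5% lie on those ends, and the mutant has 2 such libraries per condition against 1 in WT; within the first and second library sets the hs3a log2 changes were 0.15 and 0.29 at rest and 0.34 and 0.49 after activation.

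Fragment ends near the bait separate the libraries. At 86 of 689 well-read ends around Igh (12.5%), at least 5 of 6 libraries had at least 50 reads and the other 6 all had fewer, where the next best of 462 ways to split the libraries accounts for 11 ends. A difference acting on the whole genome would remove ends on other chromosomes as well, but only 0.318% of those were missing in the same libraries, and the Med1 genotype is argued against because 2 mutant and 4 WT libraries had few reads there. Loss of whole DpnII sites, as a strain difference near Igh would give, was not decided by the partner ends. Where the partner at the same site could be read, it was missing too for 18 of 32 listed ends (56.25%), against 14 of 222 other ends (6.31%). A site that lacks both ends is counted there from each of them, so the share per site is lower than 56.25%. At the remaining sites the partner end was not missing, which argues against loss of the whole site there. Strain or haplotype at Igh is not in the labels, so this stays open as an untested biological difference between animals.

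Distal VH was lower in the mutant in both conditions, and mutant replicate 1 had the lowest values. That replicate alone does not account for the difference: without it on both days the log2 difference was -0.35 (exact permutation p = 0.01, the smallest of 100 arrangements, or 0.1, the smallest possible, with replicate numbers as the unit), and mutant replicates 2 and 3 reached at most 4.91% where the lowest WT library had 5.70%. Missing VH sequence may contribute in mutant replicate 1, whose libraries had no read in 8.14% of the ends read in others at 1 to 2.6 Mb, against at most 2.08% for the other replicate numbers. An effect of Med1 and an unlabelled difference at VH between the animals of the 2 genotypes both stay open.

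Some ends on other chromosomes are shared by pairs of libraries. Of 3989 ends with at least 100 reads in WT resting replicate 1 and none in a further library, 52.7% reappeared in WT LPS + IL4 replicate 3, where the median over 132 ordered pairs was 1.10%. They reappeared with a median of 1 read, which is consistent with reads passing between libraries prepared or sequenced together; no biological explanation was tested, and the labels give no sequencing run. LPS libraries, without read numbers, shared ends across genotypes: mutant replicate 2 with WT replicate 3 (phi 0.446, 56.6% of the ends of the smaller), mutant 3 with WT 1 (0.406) and mutant 1 with WT 1 (0.379), against at most 0.281 in the first deposit. Whether this comes from such passing is open, and if it does, it could hide a genotype difference in LPS.

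For each comparison of 3 with 3 libraries, 10 splits are too few for a share under 0.05. Calls in the real split and the highest number in any other were 11 and 0 elements and 18 and 0 windows for WT activation, and 11 and 0 elements and 12 and 1 windows for mutant activation, where 1 split, the real one, gave as many. For the resting genotype they were 3 and 1 elements and 0 and 1 windows, and for the LPS + IL4 genotype 3 and 0 elements and 0 and 1 windows; with 0 windows called, all 10 splits give as many by construction. For LPS they were 0 and 10 elements, in the split of mutant replicates 1 and 3 with WT replicate 2 against the rest, which points to a structure of these libraries: it parts the 3 with the fewest covered ends (47312 to 48598) from the 3 with the most (55304 to 65512), and 2 of the former are mutant and 2 of the latter WT. For LPS windows they were 0 and 0. For the interaction the real count was 0, so all 100 drawn splits give as many by construction and decide nothing; the highest others were 3 elements and 1 window.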
